A study of Mus musculus with 4 samples.

How the data were processed

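Single nuclei of mouse placentas from 4 libraries were analysed, 2 from dams under control light (CON) and 2 from dams under chronic phase shift (CPS). The deposited counts are whole-number UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 on the mouse genome mm10 and not normalised, per the file headers and labels. The other deposited files list the barcodes and the genes of each library. The annotation release, the use of intronic reads and the settings of cell calling are not stated. Gene positions were taken from an annotation of the same genome build, which held 32158 of the 32285 gene identifiers.

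Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. Doublets were removed per library as the highest scores of a Scrublet-type simulation, up to 0.8% per 1000 nuclei. This removed 690, 840, 497 and 866 nuclei in CON 1, CON 2, CPS 1 and CPS 2, and 34926 of 38021 barcodes were kept. The kept nuclei of these libraries held 23365107, 26890905, 27585107 and 34020228 UMIs. For clustering, counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes without mitochondrial, ribosomal, hemoglobin and sex-linked genes gave 30 principal components. A graph of 15 neighbours was clustered by the Leiden algorithm at resolution 1.0, with no integration between libraries. Software was Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

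Clusters were named from markers of 23 cell classes fixed before the data were examined, and a named cluster carries the ending -like. The scoring rule was set after the data were examined. It asked for at least 3 markers raised by a log2 fold of at least 1 in at least 10% of nuclei, a mean log2 fold of at least 1 and a lead of 0.5 over the next class. In addition, 4 clusters that met the rule were left unnamed by hand after their leading genes were seen. For Cluster 6, which met the rule for parietal endoderm, the reason was that no class marker was among its leading genes. The same was true of several named clusters, among them clusters 5, 12, 13 and 21, so this reason was not applied to all clusters. Classes with at least 100 nuclei in every library were tested, which left 9 named classes and 2 unnamed clusters.

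Nuclei were not used as replicates. UMI counts were summed per library over all kept nuclei and over each class, and CPS was compared with CON by the quasi-likelihood F test of edgeR with robust dispersion, TMM factors and the default low-count filter. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Numbers of nuclei per class were tested by the same model with all kept nuclei as library size. In all, 39 gene lists were fixed before the data were examined, and 38 were tested with camera of limma at a preset correlation of 0.01 where at least 5 members were tested. The response of a class was compared with that of all other nuclei by a class and condition term with the library as a block.

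Genes were named by a rule fixed before the data were examined. It took called genes with the largest changes, with at least 20 CPM in the higher group and both libraries of one group above both of the other, the tested clock genes, and members of the gene lists with the smallest p. From these the text gives a selection made after their values were seen. Alternatives fixed beforehand were RLE size factors, no low-count filter, DESeq2, leaving out each library, the replicate numbers as a block, doublets kept, at least 1000 genes per nucleus, other clusterings at resolutions 0.5 and 2.0, genes centred within each library, fixed class composition, TMM over classes and an estimated correlation in camera. Chosen after the data were examined were free RNA subtraction, thinning of each class and library to 333269 UMIs, and leaving out the 2 low-UMI mixed clusters. Free RNA of a class was estimated from its globin share relative to that of the low-UMI mixed clusters of the same library, whose profile was then subtracted.

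The procedure was tested on simulated data with 200 changed genes per comparison. At a 2-fold change 61.2% of changed genes were recovered for all nuclei, 68.7% for spongiotrophoblast-like and 32.8% for SynT-II-like nuclei, and at 1.5-fold at most 17.9% in any comparison. Of the calls, 1.75% to 7.84% were false. The counts were drawn from the dispersion trend, with no spread of single genes around it and no effect shared by the genes of a library. The false share in the real data may therefore differ. The interaction test recovered 34.5% of genes changed in 1 class alone. Of 20 unchanged lists and 21 unchanged classes 0 were called. Genes were drawn independently of each other, so the lists were not tested under correlation between genes. Simulated free RNA of 30% was estimated as 29.9% to 30.3%. It was drawn from the same low-UMI profile that the estimate uses, with the globins of the class set to 0, so a different source of free RNA was not tested.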

Results

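The data were unique molecular identifier (UMI) counts from single nuclei of C57BL/6J mouse placentas collected at embryonic day 18.5. Pregnant mice were kept under a regular light-dark cycle (CON) or under a chronic phase shift (CPS), in which the cycle was advanced by 8 h every 5 days during pregnancy. Each group had 2 libraries, called CON 1, CON 2, CPS 1 and CPS 2. Nothing in the labels says whether the libraries of a group came from separate animals or pools, so the p-values measure only the spread between these libraries. In this order, the libraries held 9317, 10287, 7987 and 10430 barcodes with 26162378, 30674856, 31747060 and 38837238 UMIs. After filtering, 8595, 9410, 7383 and 9538 nuclei were kept, with medians of 1979, 2141, 2868 and 2465 UMIs per nucleus, so the CPS nuclei were deeper. Y-linked RNA was nearly absent from CPS 2, where Uty had 0.529 CPM (UMI counts scaled to a common library total) against 112.3 to 151 CPM in the other libraries, and Xist had 2810 CPM against 100.1 to 297.6 CPM. Changes are given as log2 fold changes of CPS over CON ± SE, with n = 2 libraries per group and positions on the mouse genome build GRCm38 (mm10).

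Clustering gave 25 clusters. Markers fixed beforehand named 15 of them as 12 classes, and 10 stayed unnamed. The labyrinth was represented by sinusoidal giant cell (S-TGC-like) nuclei, which line the maternal blood spaces, by nuclei of syncytiotrophoblast layer I (SynT-I-like) on the maternal and layer II (SynT-II-like) on the fetal side, and by endothelial-like nuclei of the fetal vessels. The junctional zone was represented by spongiotrophoblast-like nuclei, which make hormones, and by glycogen trophoblast-like nuclei, which store glycogen. The share of glycogen trophoblast-like nuclei was 13.9% ± 0.103 (SD, n = 2) in CON and 15.1% ± 0.319 (SD, n = 2) in CPS. Decidual stroma-like nuclei made up 9.45% ± 4.05 (SD, n = 2) in CON and 3.93% ± 0.363 (SD, n = 2) in CPS, and pericyte-like nuclei made up 0.554% ± 0.0431 (SD, n = 2) and 1.11% ± 0.0684 (SD, n = 2). Endothelial-like nuclei made up 3.22% ± 0.921 (SD, n = 2) in CON and 5.38% ± 0.268 (SD, n = 2) in CPS. The test of shares with edgeR called 0 of 21 classes, with 2 classes at an unadjusted p under 0.05. These were pericyte-like nuclei and Cluster 16, an unnamed cluster with 41, 32, 0 and 1 nuclei in the order of the libraries (adjusted p = 0.183). The log2 ratio of Cluster 16 was -5.84, and -0.28 with doublets kept. The adjusted p was 0.233 for pericyte-like nuclei and 0.423 for decidual stroma-like nuclei, and an exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333. Unnamed clusters held 39.2% ± 1.99 (SD, n = 2) of nuclei in CON and 35.9% ± 9.64 (SD, n = 2) in CPS. Most of these were 2 clusters of low UMI content with mixed markers, cluster 0 with 2464, 2279, 156 and 12 nuclei and cluster 19 with 58, 73, 1115 and 2962 nuclei in the order of the libraries. They split by group, and their median UMI counts were 1127 and 1304. Deeper CPS nuclei can shift such shares.

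**Figure D1:**
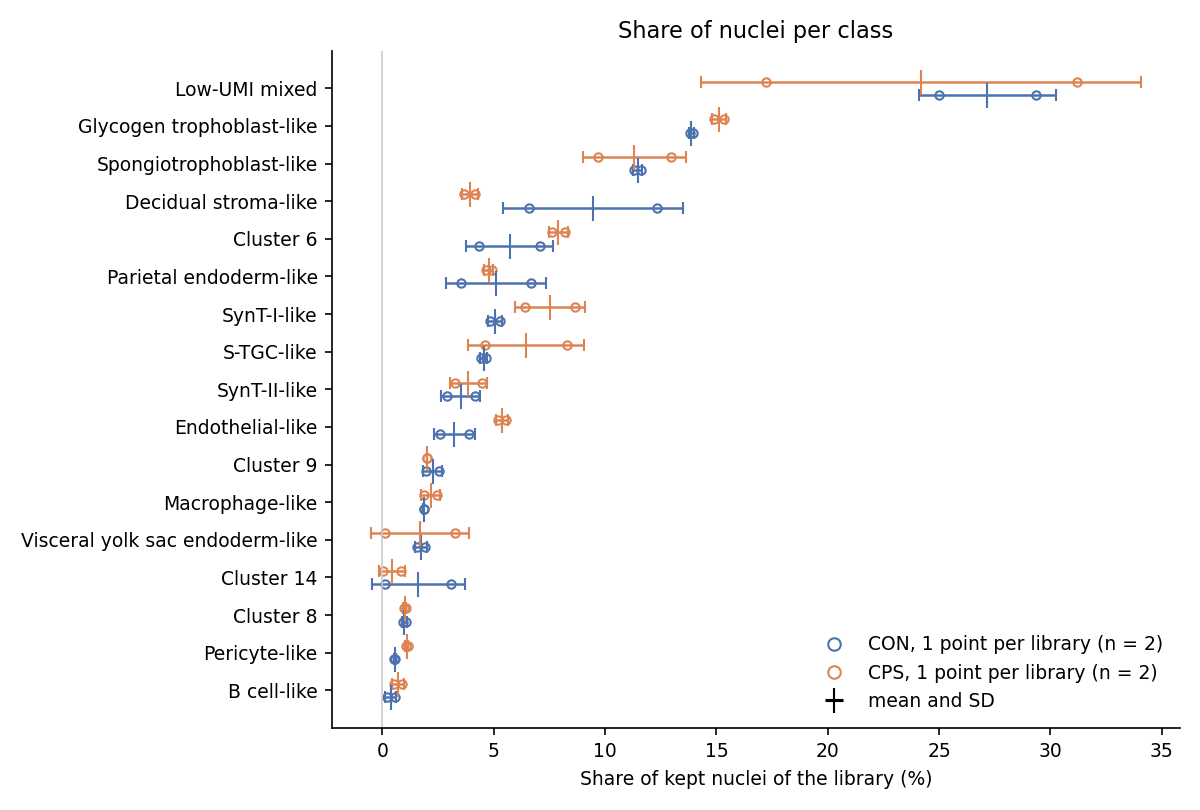
Share of kept nuclei (%) per class in CON (blue) and CPS (orange), with 1 point per library and the mean and SD of each group (n = 2). The share of decidual stroma-like nuclei was 9.45% in CON and 3.93% in CPS, and that of endothelial-like nuclei 3.22% and 5.38%, and no class passed the test.

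The comparison of all nuclei asks how the whole placenta differed after chronic phase shift. Slc26a7 (ENSMUSG00000040569, chromosome 4, 14502430 to 14621805), an anion transporter, rose by 2.91 ± 0.20, Stra6 (ENSMUSG00000032327, chromosome 9, 58063788 to 58153996), the vitamin A receptor, by 0.94 ± 0.09, and the folate receptor Folr1 by 0.51 ± 0.08 (adjusted p = 0.0217, 0.0266 and 0.0455). The largest drop among antioxidant genes was in Gclc (ENSMUSG00000032350, chromosome 9, 77754535 to 77794485), the catalytic subunit of the first enzyme of glutathione synthesis, which fell by 1.80 ± 0.08 (adjusted p = 0.0114), from 120 to 34.5 CPM. The matrix list was called down, with 3 of 23 tested members down (9 when adjusted over the list alone), among them Lum (fell by 2.14 ± 0.21) and Timp2 (fell by 1.23 ± 0.12), at adjusted p = 7.6e-09 for the list. Decidual stroma-like nuclei made up 9.45% of nuclei in CON and 3.93% in CPS. Glucocorticoid response genes had a median of -0.39 with 0 of 16 members called (6 down when adjusted over the list alone), at adjusted p = 0.000988. In all, camera called 11 of 38 lists, and all were lost when the correlation between genes was estimated, with adjusted p = 0.859 with an estimated correlation for the matrix and glucocorticoid response lists. With edgeR, 597 of 19824 genes changed, 269 up and 328 down. That count was 277 without CON 2, 0 without CPS 1 (with DESeq2 on all libraries it was 1729) and 1 without CPS 2, so no all-nuclei call held without each CPS library. Doxl1 and Doxl2, leading genes of low-UMI cluster 0, were lower in CPS in 11 of 11 classes and in all nuclei, and Lum was lower in 9 of 11 classes.

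In spongiotrophoblast-like nuclei, genes of protein folding stress and of the pregnancy-specific glycoproteins were higher in CPS. Of 17 tested genes of the unfolded protein and integrated stress response, 12 rose and 0 fell, both over all genes and adjusted over the list alone. Herpud1 (ENSMUSG00000031770, chromosome 8, 94386438 to 94395377) and Sel1l, which act in the removal of misfolded proteins from the endoplasmic reticulum, rose by 1.08 ± 0.11 and 0.92 ± 0.12, the chaperone Hsp90b1 by 0.75 ± 0.13 and the stress sensor Atf6 by 0.62 ± 0.12. The list had adjusted p = 1.77e-06, and adjusted p = 0.832 with an estimated correlation. Among pregnancy-specific glycoprotein and Ceacam genes, 11 of 20 rose and 1 fell (12 and 2 when adjusted over the list alone), with Psg17 (ENSMUSG00000004540, chromosome 7, 18813937 to 18821607) up by 1.49 ± 0.15 and Psg18 up by 1.08 ± 0.12. That list had adjusted p = 0.001, and adjusted p = 0.832 with an estimated correlation. These genes are close paralogs, so reads may be split between members. Psg17, Psg18 and Flt1 are also among the markers that named this class. Their class had a mean marker log2 fold of 1.02 in cluster 5, with most of the CON nuclei, and of 1.55 in cluster 13, with most of the CPS nuclei. A change within these nuclei was not separated from a difference in which nuclei took the name. Single genes with large rises were Aldh1l2 (ENSMUSG00000020256, chromosome 10, 83487450 to 83534140), a mitochondrial folate enzyme, by 2.35 ± 0.18 (adjusted p = 3.92e-05), the cationic amino acid transporter Slc7a2 by 2.25 ± 0.34 (adjusted p = 0.00894), the nuclear receptor Pparg (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399) by 1.32 ± 0.13 (adjusted p = 0.000157), and the leucine sensor Sesn2 by 1.07 ± 0.17. The interleukin receptor gene Il1r1 rose from 28.0 to 79.5 CPM (adjusted p = 0.000164). Flt1, which encodes a VEGF receptor and its soluble form, rose by 0.62 ± 0.13.

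Several genes of insulin and IGF signalling were lower in the same nuclei, with 7 of 19 down (9 when adjusted over the list alone). Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668), the IGF1 receptor, fell by 1.26 ± 0.14 (adjusted p = 0.000342). The list had adjusted p = 0.0123, and adjusted p = 0.832 with an estimated correlation. Gclc fell by 2.72 ± 0.15, the complement protease gene C1s1 by 4.47 ± 0.27, Hmcn1 by 3.79 ± 0.29 and the collagen Col5a2 by 3.17 ± 0.20. Col5a2 was called lower in 6 of the 11 tested classes. The glycogen synthase gene Gys1 and the branching enzyme gene Gbe1 rose by 0.67 ± 0.12 and 0.62 ± 0.12, 2 of 3 called members among 14 glycogen genes, whose list was not called (adjusted p = 0.155). In edgeR, 2914 of 14224 genes changed, 1389 up and 1525 down, from 4019637 to 5147115 UMIs per library. Most of these nuclei came from cluster 5 in CON (957 and 957 nuclei) and from cluster 13 in CPS (919 and 885 nuclei), and estimated free RNA was 25.3% and 22.4% of UMIs in CON and 18.8% and 22.6% in CPS. With free RNA subtracted, 1937 genes changed, the 2 lists above that rose held, and the insulin and IGF list was lost (adjusted p = 0.108). The called antioxidant and matrix lists were lost too (camera, adjusted p = 0.102 for both). The count was lower without CON 1 and without CON 2, and DESeq2 called 1584. At equal UMI totals Gys1 (0.99) and Gbe1 (0.48) no longer passed.

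In glycogen trophoblast-like nuclei, many glucocorticoid response, antioxidant and IGF genes were lower in CPS, and several genes of glycogen metabolism were higher. Of 16 glucocorticoid response genes 9 fell (11 when adjusted over the list alone). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a co-chaperone induced by the glucocorticoid receptor, fell by 1.75 ± 0.14 (adjusted p = 1.88e-05), from 67.9 to 20.2 CPM. The receptor gene Nr3c1 (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421) fell by 0.64 ± 0.10 and its target Tsc22d3 by 0.58 ± 0.12. The list had adjusted p = 2.48e-05, and adjusted p = 0.713 with an estimated correlation. Of 16 antioxidant genes 8 fell (8 when adjusted over the list alone), led by Gclc (fell by 2.57 ± 0.19), at adjusted p = 2.8e-05, and adjusted p = 0.713 with an estimated correlation. Of 19 insulin and IGF genes 8 fell (8 when adjusted over the list alone), among them Akt3 (fell by 1.01 ± 0.10), at adjusted p = 0.0178, and adjusted p = 0.763 with an estimated correlation. Among 15 glycogen genes 5 rose and 0 fell (5 when adjusted over the list alone), with the list itself at adjusted p = 0.0659. Ppp1r3b (ENSMUSG00000046794, chromosome 8, 35375739 to 35388139), which targets a phosphatase to glycogen, rose by 1.23 ± 0.14 (adjusted p = 0.000154), Pgm2 by 0.73 ± 0.10 and the glycogen phosphorylase gene Pygl by 0.69 ± 0.11.

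The genes with the largest rises in these nuclei included Neurl1b (3.26 ± 0.33), Pld5 (2.80 ± 0.32) and the potassium channel gene Kcnj12 (2.61 ± 0.31). The adhesion molecule gene Icam1 rose by 1.55 ± 0.18, the taurine transporter gene Slc6a6 by 1.06 ± 0.12 and the glycolytic gene Pfkp by 0.88 ± 0.11. Arhgap20 fell by 4.33 ± 0.28, the autophagy gene Wipi1 by 1.89 ± 0.16, Cyp11a1, which starts steroid synthesis, by 1.38 ± 0.15, the cholesterol exporter gene Abcg1 by 1.37 ± 0.16 and the ephrin gene Efnb2 by 1.10 ± 0.16. All 13 mitochondrially encoded genes were tested and 12 fell (12 when adjusted over the list alone), at adjusted p = 2.48e-05, and adjusted p = 0.801 with an estimated correlation. With free RNA subtracted under 5 of these 13 genes were left, so the list could not be tested. In edgeR, 2854 of 13337 genes changed, 1363 up and 1491 down, from 3218281 to 5986629 UMIs per library. Cluster 12 held most of these nuclei in CON (1158 and 1138) and cluster 21 in CPS (982 and 1316), and estimated free RNA was 34.3% and 37.2% of UMIs in CON and 26.2% and 29.5% in CPS. With free RNA subtracted, 1023 genes changed, the glucocorticoid response, antioxidant and insulin and IGF lists held and Tsc22d3 no longer passed (-1.24, adjusted p = 0.102). The called matrix and autophagy lists were lost (camera, adjusted p = 0.333 and 0.628). DESeq2 called 1454, the insulin and IGF list was lost without CPS 1 (adjusted p = 0.0674), and Tsc22d3, Pgm2 and Pygl no longer passed at equal UMI totals, where Tsc22d3 was at -0.18, Pgm2 at 0.55 and Pygl at 0.60.

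In SynT-I-like nuclei, which face the maternal side, several genes of the interferon response were higher in CPS, while several insulin and IGF, matrix and amino acid transporter genes were lower. Of 18 interferon-stimulated genes 6 rose and 0 fell (13 when adjusted over the list alone). Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), a master regulator of the type I interferon response, rose by 1.43 ± 0.24 and Bst2, which tethers enveloped viruses, by 0.68 ± 0.15. The list had adjusted p = 7.05e-06, and adjusted p = 0.948 with an estimated correlation. Of 19 insulin and IGF genes 6 fell (8 when adjusted over the list alone), with Igf1r down by 1.81 ± 0.24 and Akt3 by 1.54 ± 0.18, at adjusted p = 7.05e-06, and adjusted p = 0.948 with an estimated correlation. Stra6 rose by 2.52 ± 0.16 (adjusted p = 2.7e-07), from 47.5 to 275 CPM, Slc26a7 by 2.79 ± 0.18 and the efflux transporter gene Abcg2 by 1.44 ± 0.28. Amino acid transporter genes moved both ways, with Slc7a7 up by 1.17 ± 0.16, Slc7a8 (ENSMUSG00000022180, chromosome 14, 54722209 to 54781946) down by 1.19 ± 0.15 and Slc7a1 down by 0.87 ± 0.16, 1 up and 4 down of 17 in all (3 and 6 when adjusted over the list alone), and their list was not called (adjusted p = 0.757). The largest drops included the chromatin protein gene Hmga2 (fell by 4.09 ± 0.36), the calcium-dependent kinase gene Camk4 (fell by 3.53 ± 0.43) and Cttnbp2 (fell by 3.33 ± 0.24). Zbtb16, a glucocorticoid target, rose by 1.84 ± 0.39.

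In edgeR, 1551 of 12443 genes changed in SynT-I-like nuclei, 708 up and 843 down, from 1505421 to 3390990 UMIs per library. Of 21 matrix genes 8 fell (12 when adjusted over the list alone), at adjusted p = 3.67e-10, and adjusted p = 0.948 with an estimated correlation. Estimated free RNA was 26.4% and 22.0% of UMIs in CON and 20.2% and 23.1% in CPS, and with it subtracted 1087 genes changed and the interferon, insulin and IGF and matrix lists held. The count was 1023 without CPS 2, DESeq2 called 764, and Bst2 no longer passed without CPS 1 (adjusted p = 0.0510).

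**Figure D2:**
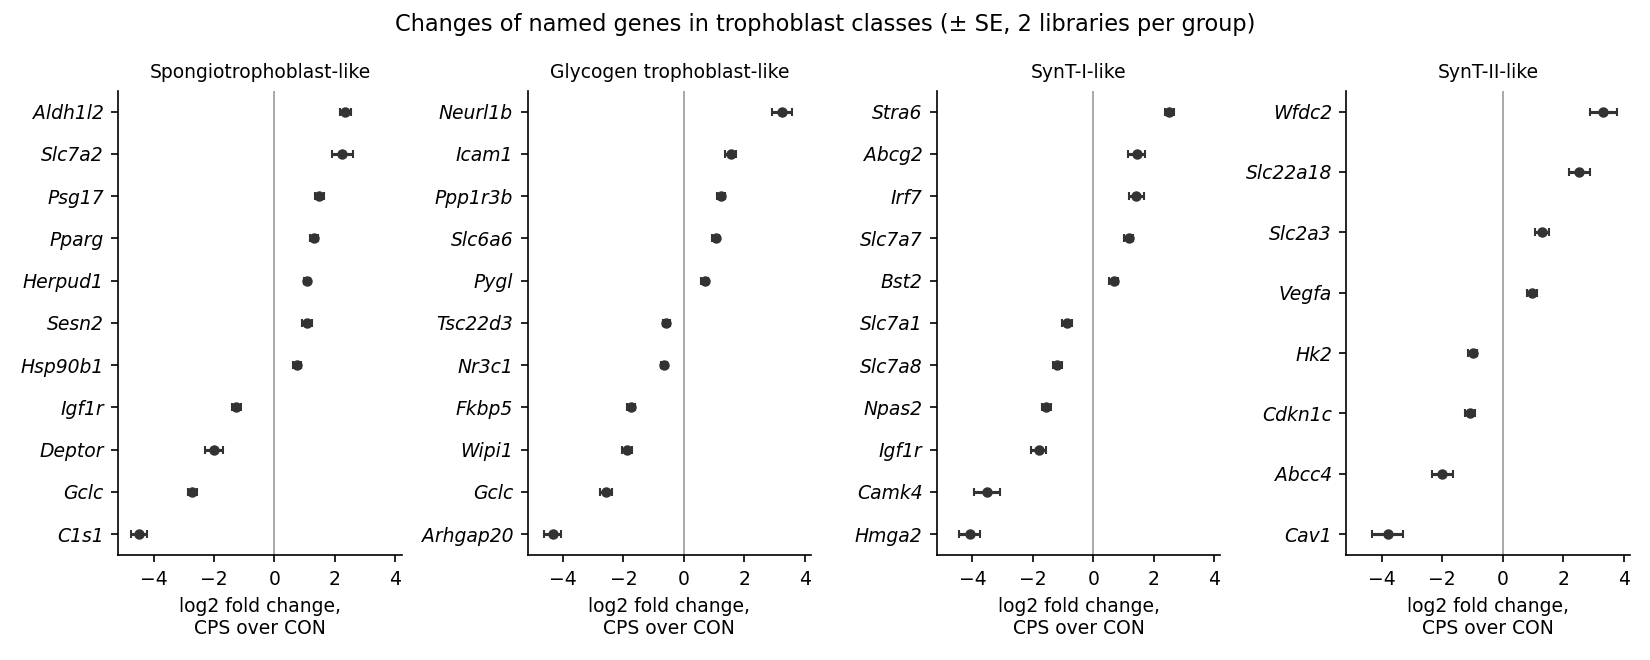
Log2 fold changes of CPS over CON with SE (2 libraries per group) for named genes in 4 trophoblast classes. Points right of 0 are higher in CPS, such as Aldh1l2 at 2.35 in spongiotrophoblast-like and Stra6 at 2.52 in SynT-I-like nuclei, and points left of 0 are lower, such as Gclc at -2.72 and -2.57 in the junctional zone.

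In SynT-II-like nuclei, which face the fetal side, matrix genes and some glucocorticoid response genes were lower in CPS. The imprinted organic cation transporter gene Slc22a18 (ENSMUSG00000000154, chromosome 7, 143473736 to 143499334) rose by 2.54 ± 0.34 (adjusted p = 0.00459), the drug efflux gene Abcb1a by 1.03 ± 0.18, the glucose transporter gene Slc2a3 by 1.30 ± 0.24, the angiogenic factor Vegfa by 0.96 ± 0.17 and Wfdc2 by 3.33 ± 0.45. Cav1, the structural protein of caveolae, fell by 3.80 ± 0.52, the efflux transporter gene Abcc4 by 1.99 ± 0.34, the hexokinase gene Hk2 by 0.99 ± 0.15 and the imprinted growth inhibitor Cdkn1c by 1.07 ± 0.16. Of 17 matrix genes 11 fell (12 when adjusted over the list alone), at adjusted p = 1.02e-16, and adjusted p = 0.367 with an estimated correlation. Of 18 interferon-stimulated genes 1 rose and 0 fell (8 when adjusted over the list alone), at adjusted p = 9.34e-06, and adjusted p = 0.62 with an estimated correlation. Of 15 glucocorticoid response genes 4 fell (5 when adjusted over the list alone), at adjusted p = 5.42e-05, and adjusted p = 0.567 with an estimated correlation. In edgeR, 730 of 11031 genes changed, 242 up and 488 down, from 835354 to 1860831 UMIs per library. Estimated free RNA was 31.1% and 34.9% of UMIs in CON and 22.7% and 21.2% in CPS, and with it subtracted 4 genes changed and the 3 lists above held. None of the genes named here passed then, with Slc22a18 at 2.35, Abcb1a at 0.79, Slc2a3 at 1.18, Vegfa at 0.78, Wfdc2 at 4.87, Cav1 at -8.02, Abcc4 at -2.32, Hk2 at -1.36 and Cdkn1c at -1.37. Of the lost calls that were still tested 96.3% kept their sign, and their median SE went from 0.24 to 0.36. The called immediate early and insulin and IGF lists were lost with free RNA subtracted (camera, adjusted p = 0.43 and 0.0812). At equal UMI totals Hk2 no longer passed (adjusted p = 0.0571). The count was 1315 without CON 1, 1415 without CON 2, 237 without CPS 1 (where Slc2a3, Vegfa and Hk2 no longer passed, adjusted p = 0.0975, 0.0700 and 0.0663) and 227 without CPS 2 (where Cdkn1c no longer passed, adjusted p = 0.0630), DESeq2 called 404, and the interferon list was lost without CON 2 (adjusted p = 0.0523).

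In S-TGC-like nuclei, the transcription cofactor gene Hopx rose by 1.39 ± 0.19 and the zinc and iron transporter gene Slc39a14 by 0.80 ± 0.11, while the transcription factor gene Tbx20 (ENSMUSG00000031965, chromosome 9, 24718138 to 24774303) fell by 3.60 ± 0.31 (adjusted p = 0.00549), Cyp17a1, an enzyme of androgen synthesis, by 1.76 ± 0.24 and Hk2 by 1.29 ± 0.17. Of 18 matrix genes 4 fell (4 when adjusted over the list alone), at adjusted p = 8.26e-09, and adjusted p = 0.921 with an estimated correlation. In edgeR, 431 of 13263 genes changed, 167 up and 264 down. Estimated free RNA was 13.6% to 16.5% of UMIs, and with it subtracted 212 genes changed, Hk2 no longer passed (-1.88, adjusted p = 0.0515) and the matrix list held. The called insulin and IGF and ribosomal protein lists were lost with free RNA subtracted (camera, adjusted p = 0.093 and 0.305). With doublets kept Hk2 was at -0.56 (adjusted p = 0.0571). The count was higher without CON 2 and without CPS 2. At equal UMI totals Hopx (1.67) and Slc39a14 (0.80) no longer passed.

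In endothelial-like nuclei, a few interferon-stimulated and imprinted genes were higher in CPS. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), an antiviral enzyme, rose by 1.97 ± 0.17 (adjusted p = 0.000134), from 92.2 to 359 CPM. Of 18 interferon-stimulated genes 2 rose and 0 fell (9 when adjusted over the list alone), at adjusted p = 1.18e-06, and adjusted p = 0.846 with an estimated correlation. Magel2, an imprinted gene outside the fixed list, rose by 2.75 ± 0.31. Of 25 imprinted genes in the list 5 rose and 1 fell (5 and 1 when adjusted over the list alone), among them Mest up by 0.92 ± 0.17 and Dlk1 up by 0.75 ± 0.15 while Smoc1 fell by 1.96 ± 0.25. That list had adjusted p = 0.0469, and adjusted p = 0.846 with an estimated correlation. Outside these lists Igfbp3 fell by 1.07 ± 0.15 and the feedback inhibitor of EGF receptors Errfi1 by 1.11 ± 0.20. In edgeR, 390 of 10690 genes changed, 158 up and 232 down, and DESeq2 called 174. Estimated free RNA was 43.5% and 43.1% of UMIs in CON and 53.7% and 52.6% in CPS, and with it subtracted 90 genes changed, the interferon list held, the imprinted list was lost (adjusted p = 0.0927) and Igfbp3 no longer passed (-1.02, adjusted p = 0.0534). The called matrix list was also lost with free RNA subtracted, and the ribosomal protein list turned down (camera, adjusted p = 0.405 and 5.54e-12). With doublets kept Errfi1 no longer passed (-0.76, adjusted p = 0.0569). The count was 623 without CPS 2, the imprinted list was lost without CON 2 and without CPS 1 (adjusted p = 0.307 and 0.256), and Mest and Dlk1 no longer passed without CPS 1 (adjusted p = 0.0517 and 0.0659).

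In macrophage-like nuclei, Stat1, the central transcription factor of interferon signalling, rose by 1.05 ± 0.22 and the interferon-induced GTPase gene Iigp1 by 1.83 ± 0.39, while the lipoprotein lipase gene Lpl fell by 1.29 ± 0.26. Of 18 interferon-stimulated genes 1 rose and 0 fell (4 when adjusted over the list alone), at adjusted p = 2.49e-08, and adjusted p = 0.705 with an estimated correlation. In edgeR, 67 of 7226 genes changed, 32 up and 35 down, and DESeq2 called 19, none of them named here. The count was 0 without CON 1, 0 without CON 2 and 153 without CPS 1, and the named genes no longer passed without CPS 2. Estimated free RNA reached 71.5% of UMIs in CPS 2, and with it subtracted 0 genes changed with edgeR while the interferon list held. Stat1 was then at 1.28, Iigp1 at 2.16 and Lpl at -1.30, and the median SE of the lost calls that were still tested went from 0.25 to 0.76. The called matrix and glucocorticoid response lists were lost with free RNA subtracted (camera, adjusted p = 0.175 and 0.167). Iigp1 and Lpl no longer passed with doublets kept (adjusted p = 0.0567 and 0.0839), Iigp1 with at least 1000 genes per nucleus (adjusted p = 0.0528), and Stat1 and Lpl at equal UMI totals (adjusted p = 0.0627 and 0.0559).

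Several proliferation genes were higher in Cluster 6, an unnamed cluster led by Ltbp1, Dmgdh and Trpv6. Of 24 proliferation genes 6 rose and 0 fell (16 when adjusted over the list alone), among them the centromere and spindle genes Cenpf (1.05 ± 0.18) and Kif11 (1.15 ± 0.22), at adjusted p = 8.09e-18, and adjusted p = 0.745 with an estimated correlation. Ppargc1a (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726), a coactivator of mitochondrial biogenesis, rose by 1.12 ± 0.14 (adjusted p = 0.0017), and Il1r1 fell by 1.55 ± 0.17 (adjusted p = 0.000794). In edgeR, 187 of 11429 genes changed, 86 up and 101 down. Estimated free RNA was 40.4% and 33.4% of UMIs in CON and 38.1% and 48.4% in CPS, and with it subtracted 22 genes changed, the proliferation list, Ppargc1a and Il1r1 held and Cenpf and Kif11 no longer passed (1.15 and 1.29, adjusted p = 0.0667 and 0.0724). The called glycolysis, cholesterol synthesis and ribosomal protein lists were lost with free RNA subtracted (camera, adjusted p = 0.351, 0.118 and 0.128). At equal UMI totals Cenpf and Kif11 were at 0.76 and 1.49 (adjusted p = 0.481 and 0.131). The count was 102 without CON 1 (where Cenpf and Kif11 no longer passed), 110 without CON 2, 638 without CPS 1 and 323 without CPS 2, and DESeq2 called 80, without Cenpf and Kif11.

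The remaining classes gave few calls. In parietal endoderm-like nuclei 24 of 10240 genes changed with edgeR. Prlr, the prolactin receptor gene, fell by 2.14 ± 0.20 and Vegfa rose by 1.57 ± 0.25 (its adjusted p was 0.113 with DESeq2, 0.0759 with doublets kept and 0.438 at equal UMI totals), and proliferation genes were called as a list (0 of 14 members, 2 up when adjusted over the list alone, adjusted p = 5.64e-07, and adjusted p = 0.689 with an estimated correlation). Prlr was called lower in 6 and higher in 1 of the 11 tested classes. In decidual stroma-like nuclei 8 of 11685 genes changed, with Tchh up by 1.45 ± 0.15, and Adam12 and Serpine2 down by 1.79 ± 0.18 and 1.48 ± 0.18. Hypoxia genes had a median of 0.38 there with 0 of 20 called (0 when adjusted over the list alone), at adjusted p = 5.1e-06, and adjusted p = 0.934 with an estimated correlation. In Cluster 9, which carried smooth muscle and fibroblast markers, 26 of 7797 genes changed, and Fkbp5 and Slc6a6 fell by 1.60 ± 0.22 and 1.45 ± 0.21. Glucocorticoid response genes there had 1 of 14 members down (5 when adjusted over the list alone), at adjusted p = 3.18e-06, and adjusted p = 0.916 with an estimated correlation. Without CON 1, CON 2, CPS 1 and CPS 2 in turn, the counts were 51, 59, 199 and 244 in parietal endoderm-like nuclei, 52, 188, 79 and 146 in decidual stroma-like nuclei, and 197, 189, 63 and 52 in Cluster 9. With free RNA subtracted, edgeR called 0 genes in each of the 3 classes, and the lists named here held. Prlr was then at -2.10 in parietal endoderm-like nuclei, Tchh, Adam12 and Serpine2 at 1.54, -1.87 and -1.86 in decidual stroma-like nuclei, and Fkbp5 and Slc6a6 at -1.63 and -2.07 in Cluster 9. The median SE of the lost calls that were still tested went from 0.21 to 0.37, from 0.18 to 0.27 and from 0.27 to 0.73 in these classes. Other called lists did not hold with free RNA subtracted. In parietal endoderm-like nuclei the matrix, hypoxia and unfolded protein lists were lost, and the ribosomal protein and prolactin family lists turned down. The insulin and IGF list was lost in decidual stroma-like nuclei, and the matrix, immediate early and ribosomal protein lists in Cluster 9.

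**Figure D3:**
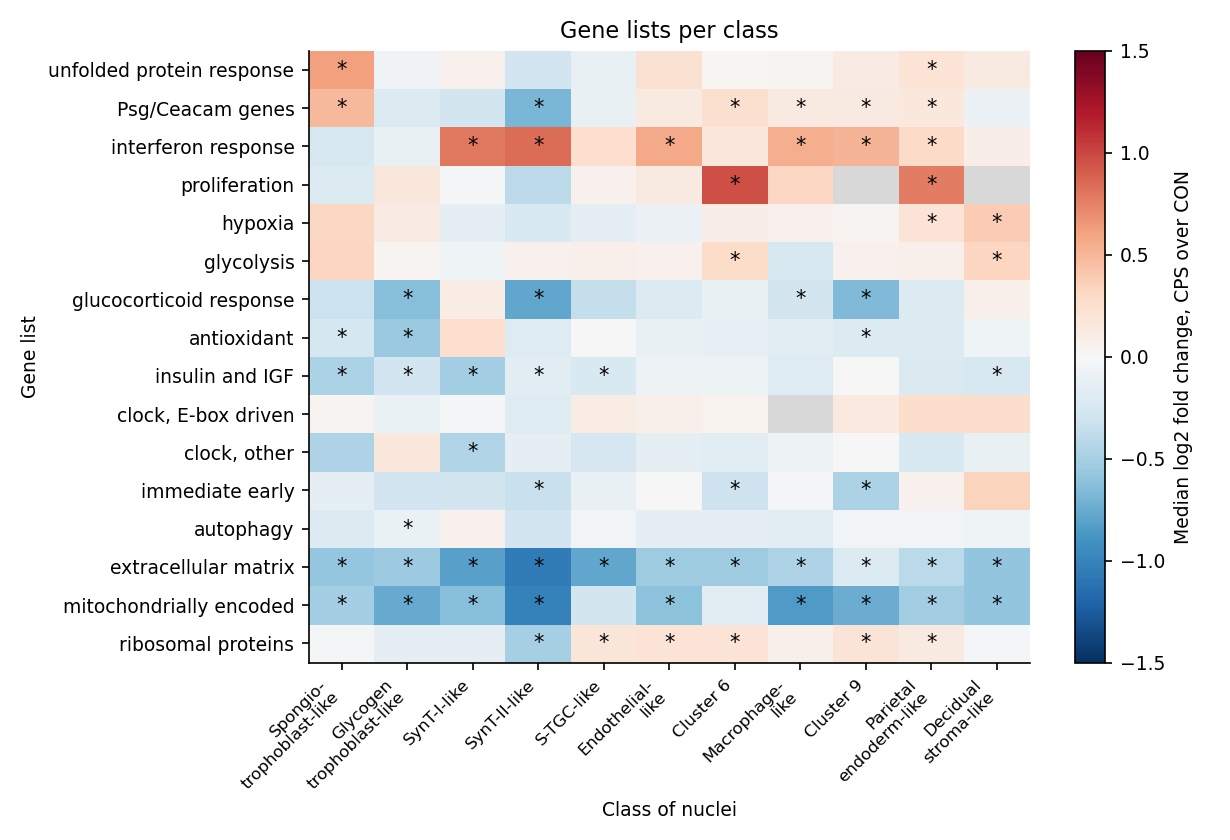
Median log2 fold change of CPS over CON (colour) for 16 gene lists (vertical) in 11 classes (horizontal), with stars where camera called the list at its preset correlation and grey where under 5 members were tested. The interferon list is starred in 6 classes and the matrix list in all 11, and no star held with an estimated correlation. With free RNA subtracted 5 of the 6 interferon and 5 of the 11 matrix calls held. In all, 27 of the 77 list calls in the classes held.

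**Figure D4:**
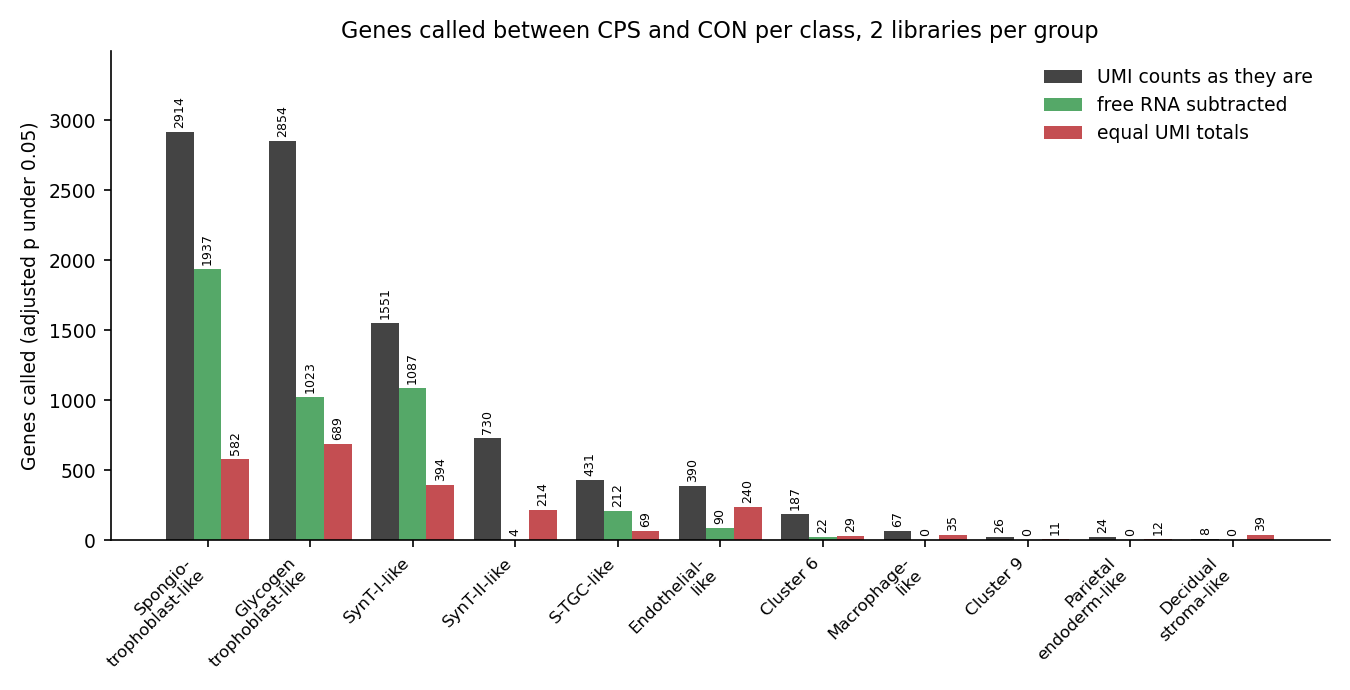
Number of genes called between CPS and CON per class (2 libraries per group) with UMI counts as they are, with free RNA subtracted and with all classes thinned to equal UMI totals. The counts were 2914, 1937 and 582 in spongiotrophoblast-like nuclei and 730, 4 and 214 in SynT-II-like nuclei.

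Clock genes were the subject of a comparison of their own, since the treatment shifts the light cycle. The labels give no time of day of collection, so a changed level cannot be told from a shifted daily rhythm. Over all nuclei 0 of 23 clock genes passed with edgeR, with 7 at an unadjusted p under 0.05. Npas2, a partner of the core clock factor Bmal1 (gene Arntl), came closest at -0.62 ± 0.11 (adjusted p = 0.053) and was called by DESeq2. In single classes 18 of 176 gene and class pairs passed, 6 up and 12 down. Of these, Npas2 was down in 2 and up in 0 of the 10 classes where it was tested, and Arntl was up in 1 and down in 2 of 11. Many genes of any kind passed in the classes described next. These were 2914 of 14224 in spongiotrophoblast-like, 2854 of 13337 in glycogen trophoblast-like and 1551 of 12443 in SynT-I-like nuclei. The number of clock gene calls was not tested against this background. In SynT-I-like nuclei activator genes of the clock fell: Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236) by 1.55 ± 0.14 (adjusted p = 6.85e-06), Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) by 0.89 ± 0.19 and Clock by 0.55 ± 0.15. There 3 of 7 genes of the list that holds them fell (3 when adjusted over the list alone), at adjusted p = 0.00925, and adjusted p = 0.948 with an estimated correlation. In glycogen trophoblast-like nuclei Arntl rose by 0.66 ± 0.12 and Hlf by 2.32 ± 0.45, while Per1, a repressor of the clock, fell by 0.50 ± 0.16 and the kinase gene Csnk1e by 0.78 ± 0.14. In spongiotrophoblast-like nuclei the repressor genes Per1 and Cry1 rose by 0.67 ± 0.14 and 0.54 ± 0.12 and Csnk1e and Rora fell by 0.61 ± 0.14 and 0.66 ± 0.16. The list of genes driven through E-boxes, which holds Per1 and Cry1, was called in none of the 10 classes where it could be tested.

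With free RNA subtracted Npas2, Arntl and Clock still passed in SynT-I-like nuclei, as did Per1, Cry1, Csnk1e and Rora in spongiotrophoblast-like and Csnk1e in glycogen trophoblast-like nuclei, while Arntl, Hlf and Per1 in glycogen trophoblast-like nuclei did not (0.53, 2.70 and -0.65, adjusted p = 0.0790, 0.0678 and 0.123). Leaving out 1 library ended the calls of Clock in SynT-I-like nuclei (adjusted p = 0.135 without CON 2, 0.0823 without CPS 1 and 0.152 without CPS 2), of Per1 and Rora in spongiotrophoblast-like nuclei (without CON 1), of Cry1 and Csnk1e there (without CON 2), of Hlf in glycogen trophoblast-like nuclei (without CPS 2) and of Per1 there (without CON 2 and without CPS 2). At equal UMI totals Arntl and Clock in SynT-I-like nuclei no longer passed (-0.84 and -0.26). The same held for Per1 and Cry1 in spongiotrophoblast-like (0.11 and 0.89) and Per1 and Csnk1e in glycogen trophoblast-like nuclei (-0.85 and -0.50). With DESeq2 the calls of Clock in SynT-I-like (adjusted p = 0.118), Per1 in glycogen trophoblast-like (adjusted p = 0.262) and Cry1 and Csnk1e in spongiotrophoblast-like nuclei (adjusted p = 0.0717 and 0.0676) ended. With doublets kept Rora in spongiotrophoblast-like nuclei was at -0.19 (adjusted p = 0.494), and Clock in SynT-I-like and Per1 in glycogen trophoblast-like nuclei no longer passed (adjusted p = 0.0519 and 0.0670). The clock list in SynT-I-like nuclei was lost without CON 2 (adjusted p = 0.0642).

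**Figure D5:**
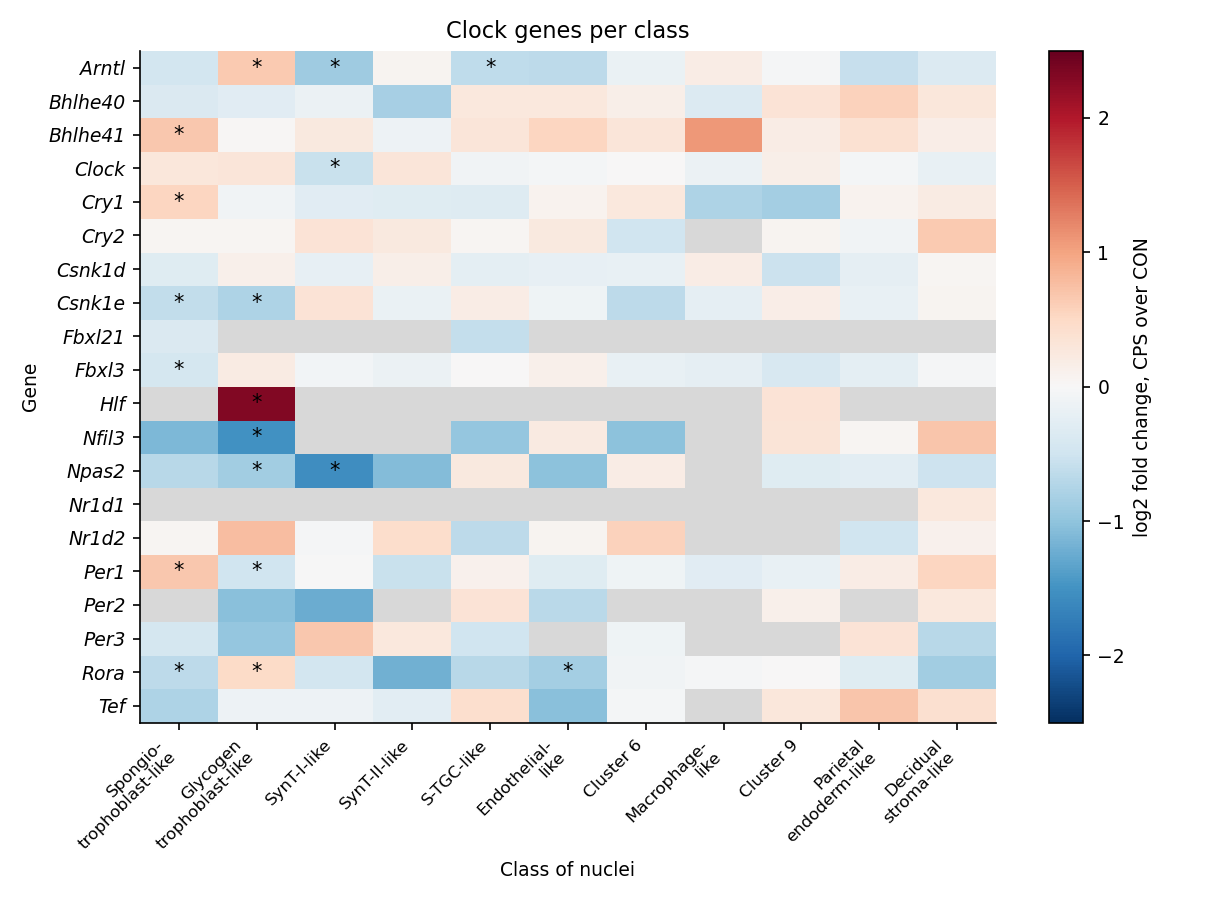
Log2 fold change of CPS over CON (colour) of clock genes (vertical) in 11 classes (horizontal), with stars for the 18 pairs that passed the test and grey where a gene was not tested. Npas2 and Arntl are lowered in SynT-I-like nuclei (-1.55 and -0.89), and Arntl is raised in glycogen trophoblast-like nuclei (0.66).

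Whether a class responded differently from the remaining placenta was tested as the change in the class minus the change in all other nuclei of the same libraries. The other nuclei included low-UMI clusters 0 and 19, which split by group, and the test was not run without them. Per1 and Cry1 rose more in spongiotrophoblast-like nuclei than elsewhere, by 0.83 and 0.78, whereas Per1 fell more in glycogen trophoblast-like nuclei (-0.67), and Arntl differed in opposite directions in glycogen trophoblast-like (1.14) and SynT-I-like nuclei (-0.90). Slc6a6 differed by 1.15 in glycogen trophoblast-like nuclei and by -1.61 in Cluster 9, and Il1r1 by 1.64 in spongiotrophoblast-like nuclei and by -2.08 in Cluster 6. Of the called genes that the naming rule took, 0 of 25 in macrophage-like and 2 of 36 in S-TGC-like nuclei passed this test. In spongiotrophoblast-like nuclei 45 of 109 did. Since 34.5% of simulated class changes were recovered, genes that did not pass are not shown to change alike. Over the 11 classes 7096 tests passed with edgeR, from 83 in macrophage-like to 1476 in spongiotrophoblast-like nuclei. The total was 4082 without CPS 1.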

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

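The tests with free RNA subtracted, at equal UMI totals and without the low-UMI mixed clusters were chosen after the data were seen, and so was the criterion for calls that were gone after the subtraction. Each value in the next 2 paragraphs stands out because the change in a class differed from the change in all other nuclei of the same libraries, tested with edgeR. Those other nuclei included the 2 low-UMI mixed clusters, which split by group.

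The number of genes with such a difference was 1476 in spongiotrophoblast-like nuclei (1211, 1628, 498 and 1126 without CON 1, CON 2, CPS 1 and CPS 2 in turn). With the same order of libraries left out, it was 1407 in glycogen trophoblast-like nuclei (796, 1128, 979 and 1384). In SynT-I-like nuclei it was 1247 (1080, 637, 920 and 824), and in SynT-II-like nuclei 772 (561, 616, 334 and 351). Endothelial-like nuclei had 744 (335, 467, 339 and 670) and Cluster 6 had 572 (295, 248, 426 and 348). Decidual stroma-like nuclei had 340 (406, 537, 368 and 342) and parietal endoderm-like nuclei 170 (93, 84, 64 and 340). Cluster 9 had 146 (201, 110, 68 and 126), S-TGC-like nuclei 139 (415, 1071, 22 and 75) and macrophage-like nuclei 83 (81, 47, 64 and 44).

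Among clock genes, the change in glycogen trophoblast-like nuclei minus that in all other nuclei was 2.19 for Hlf, 1.16 for Rora, 1.14 for Arntl, -0.67 for Per1 and -0.78 for Csnk1e (log2). In spongiotrophoblast-like nuclei it was 0.83 for Per1, 0.78 for Cry1, -0.58 for Csnk1e and -1.0 for Rora. In SynT-I-like nuclei it was -1.18 for Npas2, -0.90 for Arntl and -0.56 for Clock, and in endothelial-like nuclei -1.10 for Rora.

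More genes passed in spongiotrophoblast-like (2914) and glycogen trophoblast-like nuclei (2854) than in any other class, but not with free RNA subtracted (1087 in SynT-I-like against 1023 in glycogen trophoblast-like nuclei) or without CON 1 (2087 in SynT-I-like against 1601 and 1922). At equal UMI totals the class with the fewest calls, Cluster 9, had 1.89% of the lower junctional zone count. This cannot decide on a library difference that acts on all nuclei alike, since the test did not find changes equally well in all classes. Simulated 2-fold changes at the full UMI totals were recovered at 25.4% in Cluster 9 and at 68.7% in spongiotrophoblast-like nuclei. The sex of CPS 2, the library without Y-linked RNA, is argued against. Without that library 75.5% of the glycogen trophoblast-like and 118% of the spongiotrophoblast-like count was left. The larger number of UMIs in these classes stays open as part of the cause: at equal totals the lower of both counts was 1.48 times the highest count of the other classes, but S-TGC-like nuclei, with 2630606 to 4631253 UMIs per library, had 431 calls, and 69 at equal totals against 582 and 689. Free RNA stays open: 48.6% of the calls of both classes were kept after its subtraction, and of the lost calls that were still tested 99.7% and 98.8% kept their sign, with a median absolute log2 fold change that went from 0.81 to 0.89 and from 0.67 to 0.73 and a median SE that went from 0.21 to 0.28 and from 0.16 to 0.24, so that the lost calls do not show free RNA as the source. A response of the junctional zone to the phase shift stays open as well.

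The 47 genes called in at least 6 of the 11 classes, 34 down and 12 up in all their classes and 1 in both directions, included Doxl1, Doxl2, Lum, Timp2, Col5a2 and Prlr. Free RNA that differs between the groups may account for their calls outside the junctional zone, of which 95.1% were lost after its subtraction. That share alone cannot decide, since most calls of any gene were lost in several of these classes. Over all genes, 728 of 730 calls were lost in SynT-II-like and 330 of 390 in endothelial-like nuclei, against 652 of 1551 in SynT-I-like and 241 of 431 in S-TGC-like nuclei. Doxl1 and Doxl2 also lead low-UMI cluster 0, part of the profile that was subtracted. Of the 234 lost calls of the 47 genes, 77.4% were no longer tested, changed sign or shrank by over 1 SE, against 22.5% of the lost junctional zone calls. The subtraction also widens the error, so a change within these classes stays open for the remaining calls.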

How the results depend on the processing

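The alternatives with free RNA subtracted, at equal UMI totals and without the low-UMI mixed clusters were chosen after seeing the data. Leaving out 1 library leaves a group with 1 library, which is then assumed to vary like the other group. Of 106 gene values in the text and plots, 105 of which passed the test, 10 no longer passed with DESeq2, 8 with doublets kept, 9 without CON 1, 9 without CON 2, 13 without CPS 1, 13 without CPS 2 and 1 with at least 1000 genes per nucleus. Of those tested, 72 passed and 26 no longer did with free RNA subtracted, and 68 and 19 at equal UMI totals, and 0 reversed under any alternative. These genes were selected after their values were seen. Of all called genes that the rule named and that were tested again, 175 passed with free RNA subtracted, 211 no longer did and 14 changed sign. At equal UMI totals these counts were 249, 176 and 3, with DESeq2 460, 154 and 0, and without a library 440 to 487, 125 to 174 and 0. RLE size factors and the lack of a low-count filter ended 0 of the calls in the text and plots. The number of genes called moved by over 1.5 times as follows, and the cause was not tested except that thinning and the leaving out of a library reduce the data by construction.

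Without the low-count filter, the counts were 1265 in all nuclei, 559 in Cluster 6, 221 in Cluster 9, 478 in decidual stroma-like, 815 in endothelial-like, 135 in macrophage-like, 168 in parietal endoderm-like, 1572 in S-TGC-like and 1347 in SynT-II-like nuclei. With DESeq2 they were 1729 in all nuclei, 80 in Cluster 6, 77 in decidual stroma-like, 174 in endothelial-like, 1454 in glycogen trophoblast-like, 19 in macrophage-like, 1584 in spongiotrophoblast-like, 764 in SynT-I-like and 404 in SynT-II-like nuclei. With the replicate block they were 4 in all nuclei, 415 in decidual stroma-like, 142 in macrophage-like, 146 in parietal endoderm-like, 107 in S-TGC-like and 1804 in spongiotrophoblast-like nuclei, 9 of the 105 gene values no longer passed, and the deviations of equally numbered libraries correlated across genes at -0.18 to 0.01. With doublets kept they were 216 in Cluster 9, 64 in decidual stroma-like, 43 in macrophage-like and 270 in S-TGC-like nuclei, and with at least 1000 genes per nucleus 16 in Cluster 9, 35 in macrophage-like and 37 in parietal endoderm-like nuclei. With class composition held fixed, 1599 genes passed in all nuclei, where Lum and Timp2 were at -1.86 and -1.08.

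Leaving out each library gave 0 to 655 genes in all nuclei, 102 to 638 in Cluster 6, 52 to 197 in Cluster 9, 52 to 188 in decidual stroma-like, 436 to 623 in endothelial-like, 0 to 153 in macrophage-like, 51 to 244 in parietal endoderm-like, 372 to 1294 in S-TGC-like, 1601 to 3437 in spongiotrophoblast-like, 1023 to 2087 in SynT-I-like and 227 to 1415 in SynT-II-like nuclei. It gave 6 to 13 lists in all nuclei and 4082 to 6573 interaction tests. With an estimated correlation camera called 0 lists in all nuclei and 0 in the classes, where 11 and 77 passed with the preset value.

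With free RNA subtracted, the counts were 22 in Cluster 6, 0 in Cluster 9, 0 in decidual stroma-like, 90 in endothelial-like, 1023 in glycogen trophoblast-like, 0 in macrophage-like, 0 in parietal endoderm-like, 212 in S-TGC-like, 1937 in spongiotrophoblast-like and 4 in SynT-II-like nuclei, and 27 of the 77 list calls held, while lists with under 5 genes left could not be tested. At equal UMI totals they were 29 in Cluster 6, 11 in Cluster 9, 39 in decidual stroma-like, 240 in endothelial-like, 689 in glycogen trophoblast-like, 35 in macrophage-like, 12 in parietal endoderm-like, 69 in S-TGC-like, 582 in spongiotrophoblast-like, 394 in SynT-I-like and 214 in SynT-II-like nuclei. The test of class shares called 0 classes under every alternative run.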

Other observations

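Both tests on globins were chosen after the globin counts were seen.

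Mitochondrially encoded genes were lower in CPS in several classes beyond those described, and with free RNA subtracted under 5 were left in every class, so the list could not be tested. In SynT-II-like nuclei 9 of 11 fell (11 when adjusted over the list alone), at adjusted p = 5.17e-13, and adjusted p = 0.426 with an estimated correlation. In SynT-I-like nuclei 7 of 13 fell (10 when adjusted over the list alone), at adjusted p = 0.000349, and adjusted p = 0.948 with an estimated correlation. The median share of mitochondrial UMIs per nucleus was 0.403% and 0.265% in CON 1 and CON 2 and 0.205% and 0.252% in CPS 1 and CPS 2. Without CON 1, the library with the highest share, the list was no longer called in all nuclei and in some classes. Among these were Cluster 9 and decidual stroma-like, endothelial-like and spongiotrophoblast-like nuclei. In parietal endoderm-like nuclei its direction then turned up. Some hormone genes were also lower in SynT-II-like nuclei, with 8 of 22 prolactin family genes (10 down and 3 up when adjusted over the list alone) at adjusted p = 2.89e-06, and adjusted p = 0.415 with an estimated correlation. These are close paralogs of genes abundant in free RNA, and with free RNA subtracted the list was lost (adjusted p = 0.926). The same list was called up in Cluster 6 (4 of 22 up and 1 down, 6 and 3 when adjusted over the list alone, adjusted p = 0.0357, and adjusted p = 0.745 with an estimated correlation) and in parietal endoderm-like nuclei (3 of 21 up and 0 down, 7 and 1 when adjusted over the list alone, adjusted p = 0.0291, and adjusted p = 0.764 with an estimated correlation), where it turned down with free RNA subtracted. Of the 38 lists tested, 14 were called in none of the fits in which they were tested.

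Embryonic globin RNA was higher in both CPS libraries. It made up 0.0115% and 0.0251% of globin UMIs in CON 1 and CON 2 and 0.446% and 0.910% in CPS 1 and CPS 2, and Hbb-y had 8, 42, 794 and 3841 UMIs. More red cell RNA in total in CPS is argued against by adult globins. They made up 1.78% and 1.53% of UMIs in CON 1 and CON 2 and 0.832% and 1.68% in CPS 1 and CPS 2. The lowest CPS share was 0.47 times the highest in CON. Adult globins do not tell fetal from maternal red cells, so the fetal part of red cell RNA could not be judged from them. A less advanced fetal stage in CPS may be a source and could not be decided. At the preset correlation the proliferation list was called up in 2 classes and over all nuclei, 3 of the 10 comparisons in which it could be tested. The number of litters or pools behind each library is not known, and a difference in stage between litters stays open too.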
